A study of Homo sapiens with 24 samples.

How the data were processed

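The samples were 24 arrays of sorted human breast cancer cells, with 12 arrays from SUM159 and 12 from T47D. Per the labels, cells were treated for 72 hours with DMSO or 5 µM ID8, stained with the Aldefluor reagent and sorted. The gate for Aldefluor+ cells was set on a tube that also held DEAB, an inhibitor of the Aldefluor reaction. Total RNA was amplified and hybridised to an Affymetrix Human Gene ST array plate. The labels describe 3 separate experiments per line, and each experiment gave 1 array to each of the line's 4 groups.

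The deposited values are log2 signals from robust multiarray averaging (RMA), per the submitters' processing notes and design text. That text also states that batch effects of experiment and processing were adjusted with ComBat before limma was run on 8 pairs of groups. Versions of RMA and limma, the batches given to ComBat, and any covariates protected in it are not given in the sources used here.

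The values themselves show the adjustment. The mean of an experiment differed from its line's mean with an SD over genes of at most 0.0226, where the spread between arrays alone would give about 0.117. The difference between the lines had an SD over genes of 0.118. Fold changes within a line can also be compressed by the adjustment, by an amount that these values do not give.

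Probe sets were named through the platform's annotation table. Of 53617 probe sets, 23871 had 1 gene symbol, 1842 had several and 27904 had none in the table. Those with several or none were left unnamed and entered only an alternative. For 22569 of the probe sets with 1 symbol, the symbol was updated by gene number to the RefSeq gene table of assembly GRCh38.p14. For the 632 genes with more than 1 probe set, the probe set with the highest mean over the 24 arrays was used, which left 22395 genes. Of these, 49% had a mean below 2, a low level on the log2 scale where signal over background is small.

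The main test was limma (lmFit and eBayes) on all 24 arrays, with 8 group means and the experiment as a block within each line. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Errors given with SE come from this model and those given with SD are spreads over arrays. The 8 comparisons are those of the submitters. Comparisons that share a group share its arrays, so their results are not independent. A further 5 tests took differences of effects between fractions or lines. The numbers pair the samples because the labels state that each number marks a separate experiment. Deviations from group means correlated between -0.408 and -0.266 over the 36 pairs of arrays of the same experiment. For arrays of the same line that came from another experiment and another group they correlated between 0.0986 and 0.244. The negative values, and the positive ones too, follow when group means and experiment means have both been removed. They show that the values were adjusted by these numbers and are no separate evidence for the pairing.

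Because those means had been removed, a fit without the block counts degrees of freedom that the adjustment used. This was tested on simulated data with 200 of 22395 genes changed, 3 runs per comparison, adjusted by an empirical Bayes step modelled on ComBat with the experiment as batch and no protected covariate. For ID8 in SUM159 Aldefluor+ cells, the fit with the block recovered 75% of changes of log2 1 and 98.7% of changes of log2 2, with 2.43% false among the calls. The fit without it recovered 84.7% and 99%, with 21.9% false. For ID8 in T47D Aldefluor+ cells the shares were 69.7%, 98% and 4.92% with the block, and 83.7%, 98.7% and 22.4% without it. Changes of 1 and 2 were estimated there as 0.802 and 1.59. With the block, the false share was 6.25% for the SUM159 fractions with ID8, 5.72% for the T47D fractions with ID8 and 5.21% for ID8 in SUM159 Aldefluor- cells, above the nominal 5%, and it was 3.74%, 3.66% and 2.68% for the SUM159 and T47D fractions with DMSO and for ID8 in T47D Aldefluor- cells.

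The 37 gene lists of pathways, cell states and other cell types were fixed before the values were seen. Each was tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and limma's fry served as alternatives. Members were also counted when adjusted over the list alone. Overlaps were counted for pairs of comparisons that share no arrays. Beside them stands the count that independent lists would give, the product of both numbers of calls divided by the number of genes. All comparisons use the same estimate of spread per gene, so calls are not independent and this count may be too low a reference. RNA per collected cell was computed from the cell numbers and RNA amounts in the labels and tested with an exact two-sided sign-flip permutation test over 6 experiments.

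Named genes followed a rule. Per comparison these were the 8 highest and 8 lowest fold changes among genes called with the same sign in all 3 experiments. A call needs a mean difference that is large against its SE. Equal signs therefore nearly follow from the call and are no separate support for it. To these came the 3 members with the smallest p of each list past the threshold, along with ALDH1A1, ALDH1A3, called ALDH family members and the DYRK kinases. For a difference of effects the 5 called genes with the smallest p were named. Genes shared between comparisons, with MYL9 in T47D among them, and the values of each line beside a difference of effects were chosen after their values were seen. The groups, comparisons, tests of expression, gene rule and the other settings listed next were chosen before the data were examined. The tests of RNA per cell were chosen after the cell numbers and RNA amounts in the labels had been seen.

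Other settings were a fit without the block, each line or each set of compared groups fitted alone, and leaving out the 40% of genes with the lowest means. Others were testing all probe sets, eBayes with trend and robust settings, quantile normalization of the deposited values again, and removing experiment means before a fit without the block. Each experiment was also left out in turn. Array weights and leaving out the SUM159 DMSO Aldefluor+ array of experiment 4 were added after seeing the data. No deposited column was left unused. Scanner files and the share of Aldefluor+ cells were not analysed here. Software was R 4.3.3, limma 3.58.1, Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and matplotlib 3.10.9 for the plots.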

Results

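Gene expression was measured on 24 arrays from human breast cancer cells sorted by aldehyde dehydrogenase activity. SUM159 is a triple-negative line with mesenchymal features, and T47D is a luminal, oestrogen-receptor-positive line. Cells received DMSO, the vehicle, or 5 µM of the small molecule ID8 for 3 days. The Aldefluor reagent becomes fluorescent in cells with high aldehyde dehydrogenase activity. The Aldefluor+ cells, which the submitters take as cancer stem cells, and the Aldefluor- cells were then collected by flow cytometry. The 2 lines, 2 treatments and 2 fractions make 8 groups of 3 arrays, and each group holds 1 array from each of 3 separate experiments per line. The experiments of SUM159 are numbered 2, 3 and 4, and those of T47D 5, 6 and 7. Values are log2 signals already adjusted for batch by the authors, and 22395 named genes were tested. Arrays carry no count depth, and the number of arrays limits the precision.

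The known difference between the lines was still visible in the adjusted values, at a much reduced size. VIM, the mesenchymal intermediate filament vimentin, averaged 5.21 ± 0.039 in SUM159 and 4.46 ± 0.084 in T47D (log2, SD, n = 12 arrays per line). CDH1, the epithelial cadherin, averaged 4.90 ± 0.036 in SUM159 and 5.60 ± 0.024 in T47D. Of the genes fixed as typical of SUM159, 12 of 13 were higher in that line, and 15 of 15 fixed as typical of T47D were higher in T47D. The largest difference between the lines for any gene was 1.18 on the log2 scale, so levels were not compared between lines below, and differences within each line were. Many named genes had a low signal: 56 of the 108 called values named below for the 8 comparisons had a compared group with a mean below 2 on the log2 scale. Their folds depend on the background of the probe set and are not ratios of transcript number. For ZNF222, REP15, FGG and SLC26A1 both groups lay below 2.

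Aldefluor+ samples yielded more RNA per collected cell than Aldefluor- samples in all 6 experiments. The ratio of the fractions was 1.31-fold, with a mean log2 ratio of 0.38 ± 0.19 (SD, n = 6 experiments). SUM159 Aldefluor+ samples gave 12.9 ± 0.173 pg per cell with DMSO and Aldefluor- samples 10.6 ± 1.31 pg (SD, n = 3). The matching T47D values were 19.3 ± 1.05 and 13.8 ± 3.03 pg. An exact two-sided sign-flip permutation test over the 6 experiments gave p = 0.0312, the smallest it can give, and p = 0.0625 after adjustment over the family of 2 such tests. The amounts in the labels had been seen before this test was chosen. RNA per cell with ID8 and with DMSO did not differ by the same test, with a mean log2 ratio of -0.01 ± 0.34 (SD, 3 experiments higher and 3 lower, exact p = 1). The mean was 0.20 ± 0.30 in SUM159 and -0.21 ± 0.28 in T47D (SD, n = 3 experiments), so a value near 0 over both lines says little about either, and neither line was tested alone.

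The first question is how Aldefluor+ cells differ from Aldefluor- cells. In SUM159 with DMSO the clearest difference was in ALDH1A1, a cytosolic enzyme that oxidises retinaldehyde. ALDH1A1 was 6.99-fold higher in Aldefluor+ cells, at 5.01 ± 0.16 against 2.21 ± 0.23 (log2, SD, n = 3), with a log2 difference of 2.81 ± 0.171 (SE, adjusted p = 4.73e-07). ANKRD1, a nuclear ankyrin-repeat protein and a target of the YAP coactivator, was 4.21-fold higher (log2 2.07 ± 0.187, adjusted p = 7.17e-05). NPR3, the clearance receptor for natriuretic peptides, was 2.93-fold higher (adjusted p = 0.031), and MYL9, a regulatory light chain of non-sarcomeric myosin, was 2.21-fold higher (adjusted p = 0.0338). KIAA0040 was the remaining gene past the threshold, at log2 1.15 ± 0.181. ALDH1A3, another retinaldehyde dehydrogenase, differed by -0.01 ± 0.203 and did not pass.

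These 5 genes, all higher in Aldefluor+ cells, were the ones called by limma in this comparison, and 1780 had an unadjusted p under 0.05. In this and every other comparison, a share of 0.05 of the 22395 genes would have such a p with no change at all. Without the experiment block the count was 88. It was 3, 2 and 3 when experiments 2, 3 and 4 were left out in turn. The SUM159 DMSO Aldefluor+ array of experiment 4 had a narrower spread of values than the other 23 (interquartile range 2.05, against 2.17 to 2.33). Without this array MYL9 (adjusted p = 0.14) and KIAA0040 (adjusted p = 0.0769) no longer passed.

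Several gene groups stood higher in the same cells by small steps, although none of their members passed over all genes. Genes of G1/S and DNA replication had a median log2 difference of 0.19 over 29 measured members, 24 of them above 0, with GINS2 at 0.58 and MCM4 at 0.41; camera gave an adjusted p of 8.66e-06, and 2 members passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.112. Cholesterol synthesis and uptake had a median of 0.22 over 19 members, with HMGCS1 at 0.57 and MVK at 0.65 (adjusted p = 0.000259, 2 members adjusted over the list alone, adjusted p = 0.112 with an estimated correlation). Interferon response genes had a median of 0.26 over 22 members and IFI27 stood at 0.68 (adjusted p = 0.0304, 1 member adjusted over the list alone, adjusted p = 0.112 with an estimated correlation). Fatty acid synthesis and storage had a median of 0.10 over 16 members, with FASN, the fatty acid synthase, at 0.74 (adjusted p = 0.0408, 1 member adjusted over the list alone, adjusted p = 0.218 with an estimated correlation). Replication-dependent histones had a median of 0.35 over 13 members (adjusted p = 0.0386, and 0.218 as the adjusted p with an estimated correlation). Mitotic genes had a median of 0.10 over 31 members (adjusted p = 0.0304, and adjusted p = 0.437 with an estimated correlation). Basal and myoepithelial genes had a median of 0.18 over 12 members, with ITGB4 at 0.81 (adjusted p = 0.0304, and adjusted p = 0.112 with an estimated correlation). The last 3 lists had 0 members past the threshold adjusted over the list alone. Endothelial markers, fixed as a sign of another cell type, had a median of 0.16 over 9 members (adjusted p = 0.0408, and adjusted p = 0.169 with an estimated correlation). Without the SUM159 DMSO Aldefluor+ array of experiment 4, 6 of these 8 list calls were kept, and histones (adjusted p = 0.132) and endothelial markers (adjusted p = 0.258) were not.

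In SUM159 with ID8, as with DMSO, Aldefluor+ cells had higher ALDH1A1. ALDH1A1 was 8.13-fold higher in Aldefluor+ cells (log2 3.02 ± 0.171 SE, n = 3, adjusted p = 1.51e-07). DSP, the desmosomal linker desmoplakin, was 2.18-fold higher (log2 1.13 ± 0.11, adjusted p = 0.00022). SPINK6, a serine protease inhibitor, was higher by 1.88, LAYN, a hyaluronan receptor, by 1.70, and IQGAP2, a scaffold protein, by 1.29 on the log2 scale. Lower in Aldefluor+ cells were CCN4, a secreted matricellular protein, at 3.73-fold (log2 -1.90 ± 0.284, adjusted p = 0.0132), TGFB2, a transforming growth factor ligand, at 2.61-fold (log2 -1.38 ± 0.244, adjusted p = 0.0437), and COL6A3, a collagen VI chain, at log2 -1.05 ± 0.199 (adjusted p = 0.0446).

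The cancer-testis antigens SPANXC (log2 -2.33 ± 0.243) and PAGE2B (-2.22) were also lower. Both belong to families of near-identical copies, so the member cannot be named with certainty from a probe set. GDA, which deaminates guanine, stood at -1.56, ANKRD29 at -1.30, and the transcripts LINC01133 and USP32P2 at -1.44 and -1.41. PALMD and RIMKLB were higher by 1.14 and 1.08, and the pseudogene AADACP1 by 1.25. ALDH1A3 differed by 0.17 and did not pass.

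Among the fixed lists, mesenchymal genes stood lower in Aldefluor+ cells. Their median was -0.11 over 21 members, with COL5A1 at -0.93 and COL1A1 at -0.75; 1 member fell over all genes, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00115, and adjusted p = 0.115 with an estimated correlation). Chaperones of the endoplasmic reticulum and the unfolded protein response had a median of -0.18 over 19 members, with PDIA4 at -0.53, ERN1 at -0.65 and PDIA3 at 0.77; 2 fell adjusted over the list alone (adjusted p = 0.00115, and adjusted p = 0.115 with an estimated correlation). Targets of ATF4, the transcription factor of the amino acid response, had a median of -0.16 with 3 of 26 members above 0 (adjusted p = 0.00513, 0 adjusted over the list alone, and adjusted p = 0.4 with an estimated correlation). YAP and TAZ targets had a median of -0.06 over 18 members, of which TGFB2 passed over all genes and 1 adjusted over the list alone, with CCN1 at -0.45 and ANKRD1 at -0.44 (adjusted p = 0.0381, and adjusted p = 0.369 with an estimated correlation).

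The fractions of SUM159 with ID8 differed in 45 genes by limma, 17 higher and 28 lower in Aldefluor+ cells, with all called genes of the same sign in all 3 experiments. The count was 208 without the experiment block, and 5, 5 and 6 when experiments 2, 3 and 4 were left out. Without the SUM159 DMSO Aldefluor+ array of experiment 4, which belongs to another group, the count was 21. ALDH1A1 was the 1 gene called between fractions with both DMSO and ID8, where independent lists would share 0.0038 higher genes, and the fold changes of both comparisons correlated at r = 0.0793 across genes, which are not independent replicates.

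**Figure D1:**
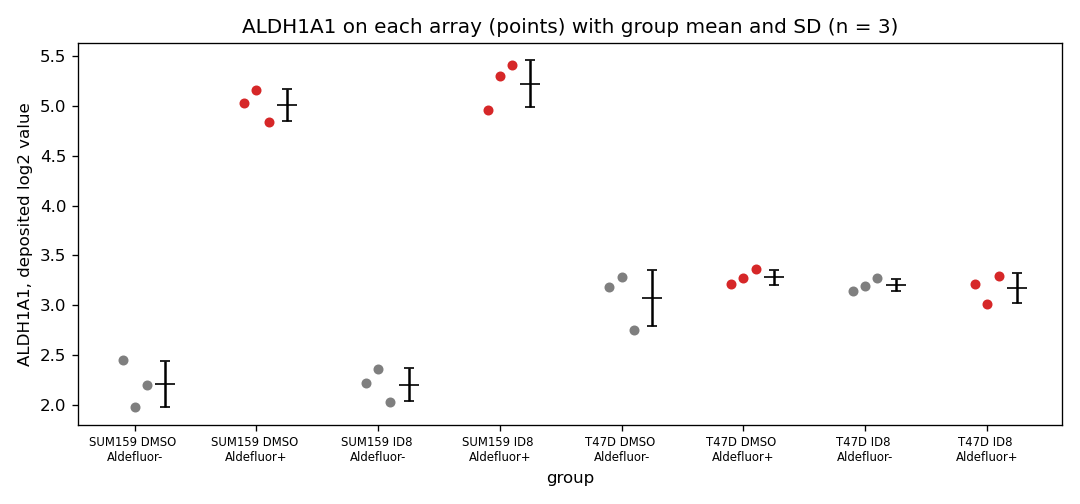
Log2 signal of ALDH1A1 in each array, by cell line, treatment and Aldefluor fraction; points are the 3 experiments and bars mark group means with their SD. SUM159 Aldefluor+ arrays lie between 4.84 and 5.41 and Aldefluor- arrays between 1.98 and 2.45, while the T47D fractions overlap between 2.75 and 3.36.

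In T47D with DMSO, SLC6A14, an amino acid transporter, was 5.8-fold higher in Aldefluor+ cells (log2 2.54 ± 0.192 SE, n = 3, adjusted p = 1.14e-05), from a low mean of 0.99 in Aldefluor- cells, SLITRK6, a neuronal transmembrane protein, 6.07-fold (log2 2.60 ± 0.312, adjusted p = 0.00105), and COX7B2, a cytochrome c oxidase subunit, 3.34-fold (adjusted p = 0.000277). NTN4, a secreted netrin, and TGFB2 were each 2.75-fold higher (adjusted p = 0.000423 and 0.018). Lower were GFRA1, a co-receptor for glial-derived neurotrophic factor, at 2.59-fold (log2 -1.38 ± 0.246, adjusted p = 0.0294), PTGES, a prostaglandin E synthase, at 2.53-fold (adjusted p = 0.00965), and ABCA12, a lipid transporter, at 2.27-fold (adjusted p = 0.000423). ALDH1A1 differed by 0.21 ± 0.171 (adjusted p = 0.802) and ALDH1A3 by 0.07, and neither passed.

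Other genes higher in T47D Aldefluor+ cells were LINC01016 (1.96), GLYATL3 (1.48) and AZGP1 (1.32), and others lower were ANGPT1, a ligand of the TIE2 receptor (-1.20), RIMS1 (-1.15), RMST (-1.13), DOCK10 (-1.08) and HDGFL3 (-1.05). By limma 34 genes were called, 20 higher and 14 lower, each of the same sign in all 3 experiments. The count was 242 without the experiment block, and 12, 7 and 5 when experiments 5, 6 and 7 were left out.

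Gene lists moved by small steps between these fractions, and none of the 5 list calls held with an estimated correlation. Basal and myoepithelial genes had a median of 0.33 over 12 members, with KRT16 at 1.04 and CDH3 at 0.67 (camera adjusted p = 0.027, 2 members adjusted over the list alone, adjusted p = 0.212 with an estimated correlation). YAP and TAZ targets had a median of 0.13 over 18 members, with CRIM1 at 0.73 and 1 member past the threshold (adjusted p = 0.0398, 4 adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). Immediate early genes had a median of 0.21 over 18 members, with FOSB at 0.91 and FOS at 0.55 (adjusted p = 0.0398, and adjusted p = 0.535 with an estimated correlation). Mitotic genes had a median of 0.14 over 31 members, with UBE2C at 0.43 (adjusted p = 0.00388, and adjusted p = 0.59 with an estimated correlation). Replication-dependent histones had a median of 0.25, with 12 of 13 members above 0 (adjusted p = 0.0398, and adjusted p = 0.535 with an estimated correlation). The last 3 lists had 0 members past the threshold, over all genes or adjusted over the list alone.

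With ID8, T47D Aldefluor+ cells had SLC6A14 as the gene with the largest positive difference, at 6.13-fold (log2 2.62 ± 0.192 SE, n = 3, adjusted p = 7.2e-06). CALCR, the calcitonin receptor, was 3.83-fold higher, from a low mean of 0.92 (adjusted p = 0.000153), NPR3 3.81-fold (adjusted p = 0.000666) and LMO4, a LIM-domain transcriptional cofactor, 3.07-fold (adjusted p = 0.000623). The chemokine CCL22 was higher by 2.04 ± 0.297 on the log2 scale, TGFB2 by 1.57 and FOS, a subunit of the AP-1 factor, by 1.42 ± 0.22 (adjusted p = 0.00534). Lower were GFRA1 at 3.37-fold (adjusted p = 0.00288), EREG, an epidermal growth factor receptor ligand, at 3.15-fold (log2 -1.66 ± 0.182, adjusted p = 0.000463), ANGPT1 at 2.78-fold (adjusted p = 0.00199) and ABCA12 at 2.68-fold (adjusted p = 7.1e-05).

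BCHE, butyrylcholinesterase, stood at -1.88, HEY2, a Notch effector, at -1.49, and AMIGO2 at -1.48. AARD and FILNC1 were higher by 1.79 and 1.60. MIR548F2 (1.81) and MIR16-2 (-1.53) are microRNA loci, and their probe sets need not measure the mature small RNA. ALDH1A1 differed by -0.03 (adjusted p = 0.984) and ALDH1A3 by 0.78 ± 0.203 (adjusted p = 0.159). ALDH1A3 was the 1 of 17 measured ALDH family members to pass with ID8 when adjusted over the list alone (adjusted p = 0.0251).

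The basal and myoepithelial list was the clearest gene group between these fractions, with 11 of 12 members above 0 and a median of 0.41. KRT16 stood at 1.08, KRT15 at 0.80 and EGFR at 0.49; 0 members passed over all genes and 5 adjusted over the list alone. Camera gave an adjusted p of 2.64e-05, and 0.00788 as the adjusted p with an estimated correlation. YAP and TAZ targets had a median of 0.21 with 15 of 18 members above 0, including FJX1 at 0.93 and CRIM1 at 0.70; 1 member passed over all genes and 4 adjusted over the list alone (adjusted p = 3.39e-05, and adjusted p = 0.0642 with an estimated correlation). Immediate early genes had a median of 0.17 over 18 members, where FOS passed over all genes and 2 adjusted over the list alone, and DUSP1 stood at 0.79 (adjusted p = 0.00302, and adjusted p = 0.187 with an estimated correlation). NF-kB targets and inflammatory cytokines had a median of 0.14 over 19 members, with CCL2 at 1.32 and CXCL2 at 0.97 (adjusted p = 0.0115, 1 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation). Genes of G1/S and DNA replication had a median of -0.18 over 29 members, with POLE2 at -0.71 and CCNE1 at 0.81 (adjusted p = 0.00248, 3 lower and 1 higher adjusted over the list alone, adjusted p = 0.333 with an estimated correlation).

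Of the genes tested, limma called 82 between the T47D fractions with ID8, 49 higher and 33 lower, each of the same sign in all 3 experiments. The count was 325 without the experiment block, and 21, 28 and 14 when experiments 5, 6 and 7 were left out. The fraction difference with DMSO and with ID8 shared 13 higher genes, among them SLC6A14, CALCR, NTN4, TGFB2, LMO4 and COX7B2, and 6 lower, among them GFRA1, ABCA12 and DOCK10. Independent lists would share 0.044 and 0.021, and 0 genes went opposite ways. Across genes, which are not independent replicates, the fold changes correlated at r = 0.204.

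The fraction difference itself depended on the line. With DMSO, ALDH1A1 differed between the fractions by 2.59 more in SUM159 than in T47D on the log2 scale (adjusted p = 0.000241). THBS1, the matrix protein thrombospondin-1, differed by 1.73 more, being 0.77 in SUM159 and -0.95 in T47D, and SNX10, a sorting nexin, by 1.54 more. SLC6A14 and COX7B2 went the other way, at -2.24 and -1.97 (adjusted p = 0.00214 for each of the last 4). This test of the difference called 15 genes, 6 with a positive and 9 with a negative difference; the count was 115 without the experiment block. Leaving out experiments 2, 3, 4, 5, 6 and 7 in turn gave 7, 10, 8, 8, 6 and 8, and it was 9 without the SUM159 DMSO Aldefluor+ array of experiment 4. The lines shared 0 called fraction genes with DMSO, where independent lists would share 0.0045 higher genes. The 5 genes called in SUM159 were all of the same sign in T47D, but only 17 of the 34 called in T47D were of the same sign in SUM159. Across genes the fold changes correlated at r = 0.0391. With ID8 the lines shared SEMA3C, lower in Aldefluor+ cells of both, while TGFB2, DKK1, EFNB2, CABLES1 and FBXO32 were lower in SUM159 and higher in T47D. Independent lists would give 0.086 opposite genes.

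The second question is what ID8 changed within each fraction. In SUM159 Aldefluor- cells ANKRD1 and MYL9 had the largest rises with ID8. ANKRD1 rose 9.23-fold, from a low signal of 1.58 ± 0.04 to 4.78 ± 0.14 (log2, SD, n = 3; difference 3.21 ± 0.187 SE, adjusted p = 2.26e-07), and MYL9 rose 6.98-fold, from 4.68 ± 0.28 to 7.48 ± 0.083 (difference 2.80 ± 0.173, adjusted p = 2.86e-07). SULT1E1, the oestrogen sulfotransferase, rose 4.83-fold (adjusted p = 2.51e-05), TGFB2 4.73-fold (adjusted p = 0.00034), EDIL3, an integrin-binding matrix protein, 4.46-fold (adjusted p = 1.66e-05), the chemokine CXCL12 3.92-fold (adjusted p = 1.46e-05) and PTGER4, a prostaglandin E2 receptor, 3.89-fold (adjusted p = 0.001). RIPOR2 rose by 1.99 on the log2 scale. CD24, a surface glycoprotein used in sorting breast cancer stem cells, was 2.02-fold lower (log2 -1.01 ± 0.135, adjusted p = 0.002). The higher ANKRD1 and MYL9 of Aldefluor+ cells with DMSO were measured against the same DMSO Aldefluor- arrays, so those results and these rises are not independent.

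Further genes lower with ID8 were PTPN22, a protein tyrosine phosphatase (-1.69 ± 0.297), EGR1, an immediate early transcription factor (-1.15 ± 0.21), HTR7 (-1.09), EPGN, an epidermal growth factor family ligand (-1.03 ± 0.176), IL31RA (-1.02), REP15 (-1.01) and CPA4 (-0.99). ALDH1A1 differed by -0.01 and ALDH1A3 by -0.32, and neither passed. By limma 62 genes were called, 42 higher and 20 lower, each of the same sign in all 3 experiments. The count was 225 without the experiment block, and 21, 16 and 8 when experiments 2, 3 and 4 were left out.

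Cholesterol genes stood higher with ID8 in these cells, with 18 of 19 members above 0 and a median of 0.30. HMGCS1 was at 0.53, DHCR7 at 0.49 and NSDHL at 0.50; 0 members passed over all genes and 4 adjusted over the list alone (camera adjusted p = 2.98e-06, and adjusted p = 0.123 with an estimated correlation). YAP and TAZ targets had a median of 0.12 over 18 members, where 2 rose over all genes and 4 adjusted over the list alone (adjusted p = 0.0403, and adjusted p = 0.378 with an estimated correlation). NF-kB targets and inflammatory cytokines had a median of 0.22 over 19 members, with IL1B at 0.89 and ICAM1 at 0.66 (adjusted p = 0.00137, 3 adjusted over the list alone, adjusted p = 0.2 with an estimated correlation). Genes of G1/S and DNA replication had a median of 0.19 over 29 members, with CCNE1 at 0.76 and MCM3 at 0.33 (adjusted p = 0.000899, and adjusted p = 0.286 with an estimated correlation). ATF4 targets had a median of -0.08 over 26 members, with SLC7A11 and DDIT4 both at -0.57 (adjusted p = 0.0444, and adjusted p = 0.471 with an estimated correlation). The last 2 lists had 0 members past the threshold adjusted over the list alone. The cholesterol and G1/S lists also stood higher in Aldefluor+ cells with DMSO, against the same DMSO Aldefluor- arrays.

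In SUM159 Aldefluor+ cells ID8 raised MYL9 3.08-fold, from 5.82 ± 0.24 to 7.45 ± 0.098 (log2, SD, n = 3; difference 1.62 ± 0.173 SE, adjusted p = 0.000778), CXCL12 2.55-fold (adjusted p = 0.00274) and the inflammatory cytokine IL1B 2.63-fold (adjusted p = 0.00832). SULT1E1 rose by 1.43 ± 0.203 on the log2 scale, AMTN, an enamel matrix protein, by 1.69 ± 0.224 and IFFO2 by 1.54. MYPN, a sarcomeric protein, was 2.55-fold lower (log2 -1.35 ± 0.176, adjusted p = 0.00518), and DKK1, a secreted antagonist of Wnt signalling, was 2.24-fold lower (log2 -1.16 ± 0.164, adjusted p = 0.00691). PTPN22 (-1.51 ± 0.297) and EGR1 (-1.06 ± 0.21) were lower here too. ALDH1A1 differed by 0.21 ± 0.171 (adjusted p = 0.744) and ALDH1A3 by -0.14.

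The long non-coding transcript LINC00619 had the largest rise, at 4.29-fold (adjusted p = 0.000778). RNU5E-4P, higher by 1.82, belongs to a family of near-identical small nuclear RNA copies and is uncertain for that reason. GDA (-1.44), MOXD1 (-1.17), ADGRF5, an adhesion receptor (-1.08 ± 0.164), and ZNF222 (-1.04) were lower. ATF4 targets had a median of -0.26, with 5 of 26 members above 0; TRIB3 stood at -0.98, NUPR1 at -0.83 and SLC7A5 at -0.65, 0 members passed over all genes and 4 fell adjusted over the list alone (camera adjusted p = 2.05e-05, and adjusted p = 0.354 with an estimated correlation). Mitotic genes had a median of -0.16, with 4 of 31 members above 0, KIF20A at -0.46 and PLK1 at -0.41 (adjusted p = 0.000133, 0 members adjusted over the list alone, adjusted p = 0.354 with an estimated correlation).

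ID8 changed 54 genes in SUM159 Aldefluor+ cells by limma, 24 higher and 30 lower, each of the same sign in all 3 experiments. The count was 397 without the experiment block, and 3, 10 and 13 when experiments 2, 3 and 4 were left out. Without the SUM159 DMSO Aldefluor+ array of experiment 4, 24 of the 54 calls were kept among 37, and array weights gave 30; EGR1, PTPN22, IFFO2, MOXD1 and ZNF222 no longer passed without it. The fractions shared 10 genes raised by ID8, among them MYL9, CXCL12, SULT1E1, EDIL3 and TLR2, and 6 lowered, among them PTPN22, EGR1 and AOX1; independent lists would share 0.045 and 0.027. Of the 54 genes called in Aldefluor+ cells, 47 were of the same sign in Aldefluor- cells, and 51 of 62 the other way. Across genes, which are not independent replicates, the ID8 fold changes in both fractions correlated at r = 0.155.

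The test of the difference between these ID8 effects called 1 gene, ANKRD1, whose rise was smaller in Aldefluor+ cells by -2.52 ± 0.264 on the log2 scale (adjusted p = 0.00121). ANKRD1 differed by 0.69 with ID8 in Aldefluor+ cells, which did not pass (adjusted p = 0.16). At an unadjusted p under 0.05 there were 1582 genes, and 36 were called without the experiment block. The count was 0 without experiment 2, 0 without experiment 3 and 2 without the SUM159 DMSO Aldefluor+ array of experiment 4.

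**Figure D2:**
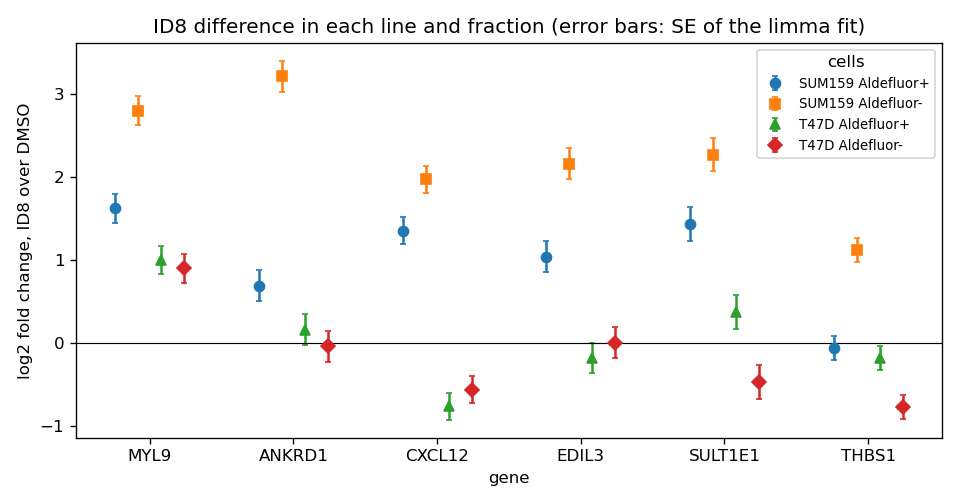
Log2 fold change with ID8 of MYL9, ANKRD1, CXCL12, EDIL3, SULT1E1 and THBS1 in each line and fraction, with error bars for the standard error (n = 3 experiments). MYL9 lies above 0 in all 4, while ANKRD1 reaches 3.21 in SUM159 Aldefluor- cells and lies at -0.04 in T47D Aldefluor- cells.

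In T47D Aldefluor+ cells ID8 raised ANXA3, a calcium-dependent phospholipid-binding protein, 3.03-fold, from 3.90 ± 0.033 to 5.49 ± 0.096 (log2, SD, n = 3; difference 1.60 ± 0.155 SE, adjusted p = 0.00042). CXCR4, the receptor for CXCL12, rose 2.86-fold (adjusted p = 0.0248), the chemokine CCL22 3.22-fold (adjusted p = 0.0219), NPR3 2.61-fold (adjusted p = 0.0154) and VTCN1, an inhibitory ligand of T cells, by 1.53 on the log2 scale. SLITRK6 was 3.71-fold lower (log2 -1.89 ± 0.312, adjusted p = 0.0154), EREG 2.12-fold (adjusted p = 0.0184), and FGG, the fibrinogen gamma chain, was at -1.09 ± 0.134 (adjusted p = 0.00343). SLITRK6 was also higher in the same DMSO Aldefluor+ arrays against Aldefluor- cells, so both results rest on these arrays. ALDH1A1 differed by -0.11 (adjusted p = 0.89) and ALDH1A3 by 0.65 ± 0.203 (adjusted p = 0.219).

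LINC00312 (1.62), TMPRSS3 (1.48) and DNAI7 (1.39) were also higher, and CA8 (-1.17), SLC26A1 (-1.01) and the small RNAs RNU1-14P (-1.42), SCARNA10 (-1.11) and VTRNA1-3 (-1.10 ± 0.165) were lower. RNU1-14P is one of many near-identical copies. ID8 changed 84 genes by limma, 65 higher and 19 lower, each of the same sign in all 3 experiments. The count was 530 without the experiment block, and 1, 4 and 4 when experiments 5, 6 and 7 were left out.

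Cell division genes stood lower with ID8 in T47D Aldefluor+ cells, and 0 of 31 mitotic genes lay above 0. Their median was -0.26, with KIF20A at -0.56, PLK1 at -0.55 and FOXM1 at -0.47; 0 members passed over all genes and 8 fell adjusted over the list alone (camera adjusted p = 7.55e-13, and adjusted p = 0.128 with an estimated correlation). Genes of G1/S and DNA replication had a median of -0.22 over 29 members, with MCM5 at -0.53 and POLE2 at -0.55 (adjusted p = 3.66e-05, 2 adjusted over the list alone, adjusted p = 0.128 with an estimated correlation). Replication-dependent histones, a family of similar copies, had a median of -0.46 with 1 of 13 members above 0 (adjusted p = 0.00106, 2 adjusted over the list alone, adjusted p = 0.128 with an estimated correlation). Interferon response genes had a median of 0.23 with 16 of 22 members above 0, including IFIT3 at 0.75 and IRF9 at 0.66 (adjusted p = 0.00219, 0 adjusted over the list alone, adjusted p = 0.0995 with an estimated correlation).

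In T47D Aldefluor- cells 4 genes passed with ID8. CXCR4 rose 4.17-fold (log2 2.06 ± 0.277 SE, n = 3, adjusted p = 0.0294), SAA1, an acute-phase protein, rose 3.13-fold (adjusted p = 0.0312) and GLYATL3 rose 2.79-fold (adjusted p = 0.0294). PTGES was 2.54-fold lower (log2 -1.34 ± 0.206, adjusted p = 0.0413). GLYATL3 and PTGES were compared with the same DMSO Aldefluor- arrays as in the fraction comparison with DMSO, so those results are not independent. ALDH1A1 differed by 0.13 and ALDH1A3 by -0.06, and neither passed. These were the genes called by limma, 3 higher and 1 lower, and 1479 had an unadjusted p under 0.05. The count was 35 without the experiment block, and 1, 2 and 0 when experiments 5, 6 and 7 were left out.

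In the same cells 3 gene lists stood higher and held with an estimated correlation. Interferon response genes had a median of 0.28 with 18 of 22 members above 0, including IFI6 at 0.52, IFIT1 at 0.99 and MX1 at 0.88 (camera adjusted p = 0.00133, and adjusted p = 0.0346 with an estimated correlation), and 0 members passed adjusted over the list alone. Breast stem and progenitor markers had a median of 0.15 with 17 of 21 members above 0; CXCR4 was the 1 member that rose, and SOX9 stood at 0.43 (adjusted p = 0.00191, 1 adjusted over the list alone, adjusted p = 0.0346 with an estimated correlation). Retinoic acid response genes had a median of 0.16 with 8 of 13 members above 0, including PLAAT4, a retinoid-inducible acyltransferase, at 0.92 and DHRS3 and CYP26A1 both at 0.43 (adjusted p = 0.00341, 1 adjusted over the list alone, adjusted p = 0.037 with an estimated correlation). ATF4 targets stood higher as well, with a median of 0.17 and 21 of 26 members above 0, including PSAT1 at 0.61 (adjusted p = 0.000344, 2 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation). Mitotic genes had a median of -0.16 with 4 of 31 members above 0 (adjusted p = 6.7e-05, 0 adjusted over the list alone, adjusted p = 0.37 with an estimated correlation), and histones a median of -0.27 over 13 members (adjusted p = 0.00777, 0 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation).

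CXCR4 and GLYATL3 rose with ID8 in both T47D fractions, where independent lists would share 0.0087 higher genes, and the fold changes correlated at r = 0.165 across genes. Of the 84 genes called in Aldefluor+ cells, 72 were of the same sign in Aldefluor- cells, as were all 4 the other way. The test of the difference between the T47D fractions in their response to ID8 called 0 genes by limma, with 1328 at an unadjusted p under 0.05 and 4 called without the experiment block. A share of 0.05 of the 22395 genes would have such a p with no change at all.

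The response to ID8 differed between the lines. In Aldefluor- cells CXCL12 responded by 2.53 more in SUM159 than in T47D on the log2 scale (adjusted p = 8.64e-05), ANKRD1 by 3.25 more (adjusted p = 3.27e-05), SULT1E1 by 2.75 more (adjusted p = 0.000382), EDIL3 by 2.16 more (adjusted p = 0.00162) and THBS1 by 1.89 more (adjusted p = 0.000505). This test called 15 genes, 12 with a larger and 3 with a smaller value in SUM159. The THBS1 result and its fraction difference with DMSO rest on the same DMSO Aldefluor- arrays of both lines, so they are not independent. With ID8 in Aldefluor+ cells THBS1 differed by -0.06 in SUM159 and -0.18 in T47D, and neither passed. In Aldefluor+ cells CXCL12 again responded by 2.11 more in SUM159 (adjusted p = 0.00108). NTN4 and FSTL1, a secreted follistatin-like protein, went opposite ways, NTN4 by -0.90 in SUM159 and 1.09 in T47D and FSTL1 by -0.80 and 0.82 (differences -1.99 and -1.62, adjusted p = 0.00116 and 0.00108). MAP2, a microtubule-associated protein, and COL12A1, a collagen XII chain, had differences of -1.46 and -1.17 (adjusted p = 0.00243 for both).

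The test in Aldefluor+ cells called 74 genes, 30 with a positive and 44 with a negative difference. Without the experiment block the counts were 582 in Aldefluor+ and 82 in Aldefluor- cells. Leaving out experiments 2, 3, 4, 5, 6 and 7 in turn gave 22, 18, 64, 29, 15 and 22 in Aldefluor+ cells, and 13, 9, 5, 11, 6 and 6 in Aldefluor- cells. The lines shared 1 gene raised by ID8 in Aldefluor+ cells, MYL9, which rose by 1.00 ± 0.173 in T47D (adjusted p = 0.0219), and 2 lowered, H1-10, a linker histone, and SEMA3C. Independent lists would share 0.07 and 0.025. NTN4 and FSTL1 were called in opposite directions, where independent lists would give 0.11 such genes. Only 23 of the 54 genes called in SUM159 were of the same sign in T47D, and fold changes correlated at r = -0.0368 across genes. In Aldefluor- cells the lines shared 0 called genes, with 0.0056 shared higher genes for independent lists.

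**Figure D3:**
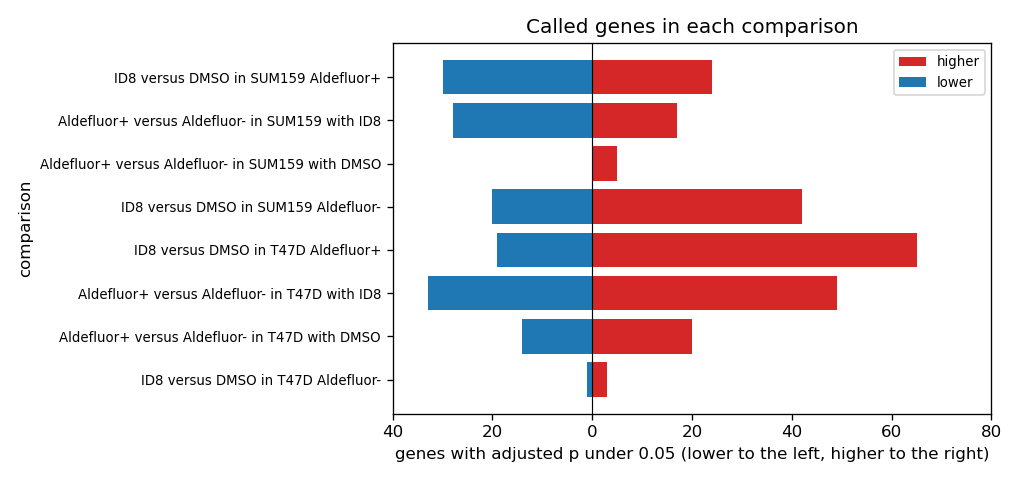
Number of genes higher and lower at an adjusted p under 0.05 in each of the 8 comparisons of sorted SUM159 and T47D cells, from limma with experiment as a block. The T47D Aldefluor+ response to ID8 holds 84 genes and the T47D Aldefluor- response 4. Of the 84 genes, 72 had the same sign in Aldefluor- cells, and the test of the difference between these responses called 0 genes.

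The DYRK kinases were named beforehand because ID8 has been described as an inhibitor of that family. The differences in DYRK1A, DYRK1B, DYRK2, DYRK3 and DYRK4 ran from -0.72 for DYRK2 (T47D fractions with DMSO, adjusted p = 0.249, the lowest of all) to 0.50 for DYRK1B (T47D Aldefluor+ cells with ID8, adjusted p = 0.528). In SUM159 Aldefluor+ cells DYRK1B, DYRK3 and DYRK4 had means below the low level of 2 with both treatments, so the lack of a call there says little. Of 37 gene lists, 16 passed in at least 1 of the 8 comparisons and 21 in none, among them ALDH family members, epithelial, Notch, Wnt, Hedgehog, p53 and TGF-beta lists. Leukocyte markers, adipocyte and fibroblast markers and the markers of the other cell line were also among those that passed in none.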

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

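The tests of collected RNA, of a poor sort, of another ALDH gene and of the mitotic genes, as well as the counts over other splits of the samples, were chosen only after the results were seen.

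The response to ID8 in SUM159 Aldefluor- cells differed from that of T47D in 15 genes by the test of the difference, with ANKRD1 at 3.25, SULT1E1 at 2.75, CXCL12 at 2.53, EDIL3 at 2.16 and THBS1 at 1.89 (SUM159 minus T47D, log2). Shrinkage of T47D values by the authors' adjustment stays open. It would also shrink their residual spread, and the median ratio of residual SDs, T47D over SUM159, was 0.902 over the 15 genes (quartiles 0.626 to 1.24). Their median ID8 differences were 0.472 in T47D and 1.37 in SUM159. The ratio cannot decide, since the spread before the adjustment is not known and the adjustment may itself have changed it. Unequal collection of RNA from ID8 and DMSO samples stays open, since 1 experiment bears on it: in experiment 2 the ID8 sample gave less RNA (1363 against 1992 ng), and the 21 genes called without that experiment had a median signed difference of 1.22 in it, with 20 of 21 in the same direction. A difference in biology between the lines stays open and was not tested further.

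ALDH1A1 separated the SUM159 fractions and not the T47D fractions, and the difference between the lines with DMSO was 2.59 (log2). Shrinkage of the T47D values of this gene stays open. The ratio of its residual SDs, T47D over SUM159, was 0.827, but the spread before the adjustment is not known. With DMSO 34 genes were called between the T47D fractions, against 5 in SUM159, so the T47D fractions were not alike. How cleanly the sort parted them stays open, since a count of called genes does not measure purity. Another ALDH family transcript in its place stays open: with DMSO 0 of 17 members passed adjusted over the list alone, but the highest upper 95% bound was 1.06, for ALDH3B1, and with ID8 ALDH1A3 passed at 0.78 (adjusted p = 0.0251 over the list alone), with an upper bound of 1.21. Enzyme activity set at the protein level stays open, since only RNA was measured.

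Mitotic genes stood lower with ID8 in both T47D fractions, with medians of -0.26 and -0.16, though neither call held with an estimated correlation (adjusted p = 0.128 and 0.37). A trend of fold change with mean level is argued against by 10000 random lists matched on mean level, of which 0 had a median as low in either fraction (lowest -0.139 and -0.105). Less RNA collected from T47D ID8 samples cannot be told apart from the treatment, since all 3 experiments had less; in SUM159 Aldefluor+ cells the list stood at -0.156 although ID8 samples gave more RNA in all 3 experiments, which goes against it but comes from the other line. Fewer cycling cells could lower the list too. The G1/S list, lower in Aldefluor+ cells, did not pass in Aldefluor- cells (camera adjusted p = 0.579). Replication-dependent histones were lower in both fractions, with medians of -0.46 and -0.27 (camera adjusted p = 0.00106 and 0.00777). Neither histone call held with an estimated correlation (adjusted p = 0.128 and 0.235), so fewer cycling cells stay an open explanation.

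The other results whose difference between groups passed its own test are values only. In SUM159 the ID8 response differed between the fractions in 1 gene, ANKRD1, by -2.52. In Aldefluor+ cells the ID8 response differed between the lines in 74 genes, with CXCL12 at 2.11, NTN4 at -1.99, FSTL1 at -1.62, MAP2 at -1.46 and COL12A1 at -1.17. The fraction difference with DMSO differed between the lines in 15 genes, with THBS1 at 1.73, SNX10 at 1.54, COX7B2 at -1.97 and SLC6A14 at -2.24.

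For each of the 8 comparisons the 6 arrays allow 10 splits, too few for a share under 0.05. Of these, 4, with the real one among them, keep the pairing by placing 1 array of each experiment in each group. The others put both arrays of an experiment into the same group. In each comparison 1 of the 10 splits, the real one, gave as many genes as observed. The highest count of any other split was 1 in each SUM159 comparison, against 54, 45, 5 and 62, and 0 in each T47D comparison, against 84, 82, 34 and 4. Between the lines the highest other counts were 1, 0 and 0, against 74 for the ID8 response in Aldefluor+ cells, 15 for that in Aldefluor- cells and 15 for the fractions with DMSO, with 1 of 10 splits as large in each. For the difference of ID8 responses between fractions there are 4 splits per line, again too few: in SUM159 the real count was 1 and the highest other 0, and in T47D all 4 splits gave 0.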

How the results depend on the processing

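Array weights and leaving out the SUM159 DMSO Aldefluor+ array of experiment 4 were chosen after the data were seen. The called genes of the 8 comparisons were named only if of the same sign in all 3 experiments, so most settings could not turn their direction and are no test of it. The fit with no experiment block kept 124 of 124 called named values and 39 of 39 list calls. That is no test of them: in this balanced design the fold changes stay the same without the block. With experiment means already removed, the fit only gains degrees of freedom. Of the 124 values, quantile normalization kept 122, array weights 120, all probe sets 79 and the compared groups alone 11. Each line fitted alone kept 67 of 109. Without experiment 2, 3 or 4, 30, 38 and 33 of 70 called values that use SUM159 were kept, and without experiment 5, 6 or 7, 33, 36 and 29 of 69 that use T47D. Without the 1 SUM159 array named above 52 of 70 were kept. Of 39 list calls 4 held with an estimated correlation, 17 with fry and 37 with array weights, and 17 of 19 in SUM159 held without that array. Low counts in fits of the compared groups alone, of 1 line alone or without an experiment come with fewer arrays; other causes were not tested. Below, results are ordered as SUM159 ID8 in Aldefluor+, fractions with ID8, fractions with DMSO and ID8 in Aldefluor-, then the same for T47D.

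With no experiment block the counts were 397, 208, 88 and 225 in SUM159 and 530, 325, 242 and 35 in T47D. The differences of effects gave 36 and 4 within SUM159 and T47D, and 582, 82 and 115 between the lines (ID8 in Aldefluor+, ID8 in Aldefluor-, fractions with DMSO). Among named values and lists, 29 further values and 1 further list were called with no block, and no call was lost. The self-test above gave a high share of false calls for the fit with no block. Experiment means removed first, again with no block, gave 475, 227, 113 and 259, then 563, 351, 288 and 41, and 46, 7, 647, 104 and 134 for the differences of effects. The fit to these values was not part of the self-test.

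Each line fitted alone gave 17, 16, 2 and 22 in SUM159, and 40, 65, 24 and 2 in T47D. The compared groups alone gave 0, 0, 2 and 2, then 0, 0, 2 and 0, and 0, 4 and 0 between the lines. For the next settings mainly counts that moved well away from the main fit are given. Without the dim genes, ID8 in Aldefluor+ cells gave 97 in SUM159 and 133 in T47D, the T47D fractions with DMSO 62, the SUM159 difference of effects 4, and ID8 between the lines 165 and 24. All probe sets gave 35 and 21 for the first SUM159 results, 55 for ID8 in T47D Aldefluor+ cells, 0 in T47D Aldefluor- cells and 49 between the lines in Aldefluor+ cells. Trend and robust settings gave 139 and 11 (SUM159 ID8 in Aldefluor+, fractions with DMSO), 163, 66 and 9 (T47D ID8 in Aldefluor+, fractions with DMSO, ID8 in Aldefluor-), 5 for the SUM159 difference of effects, and 232 and 23 for ID8 between the lines. Array weights gave 30 for ID8 in SUM159 Aldefluor+ cells. Quantile normalization gave 3 for the SUM159 difference of effects, 2 higher and 1 lower, and 3 higher and 0 lower for ID8 in T47D Aldefluor- cells.

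Leaving out an experiment, or the 1 array, gave ranges of 3 to 37, 5 to 21, 2 to 4 and 8 to 60 in SUM159, and 1 to 4, 14 to 28, 5 to 12 and 0 to 2 in T47D. Differences of effects ranged from 0 to 2 in SUM159, 0 to 0 in T47D, and 15 to 83, 5 to 16 and 6 to 10 between the lines. The log2 ratio of RNA per cell ranged from 0.322 to 0.419 between fractions and from -0.096 to 0.0957 with ID8. Signal over background limits the 49% of genes below a mean of 2.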

Other observations

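The test of actin and serum response factor genes used a list written after the called genes had been seen, and its prediction was written before that list was tested.

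Gene groups also differed between the lines in their response to ID8, as values of SUM159 minus T47D, but none of these calls held with an estimated correlation. ATF4 targets stood lower in SUM159, with medians of -0.34 in Aldefluor+ and -0.22 in Aldefluor- cells and 2 of 26 members above 0 in each (camera adjusted p = 4.85e-06 and 2.68e-05, and adjusted p = 0.191 and 0.241 with an estimated correlation). Interferon response genes were lower in Aldefluor+ cells, with a median of -0.38 and 4 of 22 members above 0 (adjusted p = 0.00119, and adjusted p = 0.0551 with an estimated correlation). Cholesterol genes were higher in Aldefluor- cells, with a median of 0.35 and 15 of 19 members above 0 (adjusted p = 0.00101, and adjusted p = 0.241 with an estimated correlation), as were NF-kB targets, with a median of 0.25 and 17 of 19 above 0 (adjusted p = 0.011, and adjusted p = 0.241 with an estimated correlation). Breast stem and progenitor markers were lower in Aldefluor- cells, with a median of -0.18 (adjusted p = 0.00245, and adjusted p = 0.0659 with an estimated correlation).

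Small RNAs made up 8 of the 84 genes that ID8 changed in T47D Aldefluor+ cells, 1 higher and 7 lower, or 9.52% against 6.6% of the genes tested. The lower ones included VTRNA1-3, a vault RNA, and the small nucleolar RNAs SNORA78 and SNORA21. In T47D Aldefluor- cells limma called 0 small RNAs among its 4 genes. Whether the share of small RNAs differs between fractions was not tested.

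The rise of MYL9 and ANKRD1 in SUM159 Aldefluor- cells led to a hypothesis, that targets of actin dynamics and serum response factor rise with ID8 in these cells. Of 44 listed genes 42 were measured, and 32 of these were called in no comparison. Of the 10 called in any, 8 rose with ID8 in these cells and EGR1 fell, against the hypothesis (log2 -1.15, adjusted p = 0.0289). Among the 32, 24 lay above 0, with a median of 0.15, and camera gave p = 4.47e-06, or p = 0.00494 with an estimated correlation, which is consistent with the hypothesis. The list shares 4 genes with the immediate early list and 3 with YAP and TAZ targets, so these could account for part of it. In SUM159 Aldefluor+ cells the same list had p = 0.56, and in T47D 0.00549 in Aldefluor+ and 0.0266 in Aldefluor- cells (0.0598 and 0.123 with an estimated correlation). The difference between the lines in Aldefluor- cells had p = 0.0427, or p = 0.155 with an estimated correlation, so a response confined to SUM159 is not shown.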
